A study of Mus musculus with 2 samples.

How the data were processed

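H3K9me3 ChIP-seq peaks from whole liver of mouse embryos at day 14.5 were analysed, from 2 biological replicates in 1 group; per the labels, each sample combines 3 technical replicates and each pool holds embryos of both sexes. The samples carry the names replicate 1 and replicate 2 as in the labels. No input or control profile was analysed here.

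The authors deposited 4 peak lists in narrowPeak format on build mm10: 1 per replicate, 1 from both replicates pooled, and a replicated list derived from the other 3. Per the notes deposited with the files, the list of replicate 1 was made from its alignments and 2 further files, and that of replicate 2 from its alignments and 1 further file; their role is not stated. The aligner, the peak caller and their thresholds are not given in the sources used here. Each deposited row gives a fold enrichment, a ratio read here as enrichment over control from its values and format, and −log10 of the p-value and of the q-value of the peak, all as the authors' caller gave them. These values were used only within a list, to describe, rank, filter or compare its peaks. The lowest −log10 p in the lists was 2.03. Because the lists hold no read counts, depth is unknown, and the number of peaks depends on depth, on the control and on the caller's threshold, none of which can be held equal here. Intervals on shares are 95% Wilson binomial intervals and cover counting error over peaks only.

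Rows that overlapped would have been merged, but none did. Coordinates are printed 1-based. The genome was GRCm38 (patch release 6), whose 21 chromosomes were used; no peak ended beyond a chromosome end. Genes came from the GENCODE basic annotation, mouse release M 21. Peaks on the 44 contigs outside the chromosomes (5.25 Mb, against 2647.5 Mb of chromosome sequence without gaps) were left out of the location tests, since they cannot be rotated along a chromosome, and are given with the flagged results. They remained in the named strongest peaks.

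Location tests used the replicated list, which draws on both samples, with 1215 peaks on chromosomes. Chance was set by rotating all peaks of a chromosome together by a random offset along its sequence without gaps, which keeps widths, numbers per chromosome and clustering: 10000 rotations, or 1000 for base composition. Permutation p-values count the real placement once, so the smallest possible is 0.0001 one-sided and 0.0002 two-sided, or 0.002 two-sided for base composition. Replicate overlap was tested one-sided with a minimum overlap of 1 base, all else two-sided. Benjamini-Hochberg adjustment ran within each family: 13 gene lists, 4 feature classes by peak midpoint (in the order promoter, exon, intron, intergenic), 7 sequence measures and 21 chromosomes. Chromosome counts were tested by an exact binomial test against ungapped length. Strength was compared by 100000 resamples across peaks. A gene counted as overlapped when its body extended by 5 kb held part of a peak, and 10000 random gene sets in 20 length bins served as a second null. Primer binding sites were exact 18-base matches on either strand within 5 kb of a peak.

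The tests of the report, the gene lists and the alternatives were fixed before the data were examined, except where said below; the closing section says which of its own tests were not. The family lists take genes by symbol, and their restriction to protein-coding genes was added once the annotation was seen. Named items followed a fixed rule: the 20 replicated peaks with the highest fold enrichment, with the gene they overlap or the gene with the nearest start; up to 8 members per list in order of fold enrichment; the 10 protein-coding genes with most covered bases; and chromosomes past an adjusted threshold of 0.05. Alternatives replaced the replicated list by either replicate's own list, by the pooled list or by the 50% of its peaks with the higher −log10 p, merged peaks within 10 kb, and changed overlap rules, windows, nulls and the mismatches allowed; a list of replicated peaks present in both own lists, a list without the 2 densest windows of 100 kb, and the first 5 Mb with that list or with merged peaks were added after seeing the data. No list of high-signal artefact regions was used here.

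The functions were tested on simulated data. With 60 zinc finger genes given an artificial peak among random ones, that list had an adjusted p of 0.013, the smallest that the rotations drawn there allow. When 50% of the peaks were copied from another list, 50% were found to overlap. Random placements gave p-values under 0.05 in 0.0625 of 80 feature tests and in 0 of 40 tests of the 2 largest gene lists. Each peak was placed on its own there, so this does not check peaks that cluster as the real ones do. All 20 peaks planted near proline sites were found. Peaks drawn by G+C content alone gave 0.933 times the expected number in zinc finger genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.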

Results

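Trimethylation of lysine 9 on histone H3 (H3K9me3), a mark of heterochromatin and silenced repeats, was mapped by ChIP-seq in whole liver of mouse embryos at day 14.5. At this stage the organ is both a developing liver and the main site of blood formation. Both samples belong to 1 group of 2 biological replicates, each from a pool of male and female embryos, and there was no second condition. The design therefore asks how far the replicates share peaks, and where in the genome the peaks of the authors' replicated list lie. The deposited lists hold peaks and no read totals, so the sequencing depth of each replicate is unknown.

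The replicates differed widely in the number of peaks called. Replicate 1 had 5441 peaks covering 1622.4 kb, and replicate 2 had 614 peaks covering 200.2 kb, a ratio of 8.86 in number. The authors' list from both replicates pooled held 2567 peaks, and their replicated list, which draws on the other 3 lists, held 1346 peaks covering 575.5 kb. Peaks were short, with a median width of 327.5 bases in the replicated list, and the longest spanned 4465 bases. Median fold enrichment, as given by the authors, was 3.35 in replicate 1, 3.47 in replicate 2 and 3.50 in the replicated list. Most peaks were weak. Only 18.6% of replicate 1 peaks, 9.28% of replicate 2 peaks and 22.4% of replicated peaks had a deposited q-value of 0.05 or less. Every replicated peak was a peak of the pooled list. Of the 1346 peaks, 455 (33.8%) overlapped a peak of both replicates' own lists, 778 overlapped replicate 1 alone, 37 overlapped replicate 2 alone and 76 overlapped neither. The replicated list thus rests more on replicate 1 than on replicate 2.

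Most of what replicate 2 showed was also seen in replicate 1. On the 21 chromosomes, 423 of 509 replicate 2 peaks (83.1%, 95% Wilson interval 79.6 to 86.1) overlapped a replicate 1 peak by at least 1 base, against a mean of 0.686 peaks when the lists were rotated against each other along the chromosomes. In the other direction, 377 of 5277 replicate 1 peaks (7.14%, interval 6.48 to 7.87) overlapped replicate 2, against 0.679 in rotations. Neither count was approached in 10000 rotations, whose highest values were 24 and 22, and the one-sided permutation p was 0.0001 in both directions, the smallest that the rotations can give. When replicate 1 was limited to its strongest peaks by −log10 p, as many as replicate 2 lists, 39.5% of these overlapped replicate 2, and 49.1% of replicate 2 peaks overlapped them. Requiring an overlap of 50% of both peaks lowered the shares to 37.9% of replicate 2 and 3.66% of replicate 1.

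Peaks of replicate 1 that were shared had higher enrichment. The overlapping peaks had a median fold enrichment of 4.11, against 3.35 for the others, and their mean log2 fold enrichment was higher by 0.23 (two-sided permutation test across peaks, p = 1e-05, the smallest that 100000 resamples can give). The share overlapping replicate 2 was 17.4% (15.5 to 19.6) in the highest quartile by fold enrichment, and 5.38%, 2.35% and 3.41% in the quartiles below, from the lowest up. In replicate 2 the difference was 0.03 on the log2 scale and did not pass the test (permutation p = 0.433). With −log10 p as the measure of strength, overlapping replicate 2 peaks were stronger by 0.734 (permutation p = 0.00076). Peaks within a list are not independent replicates.

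**Figure D1:**
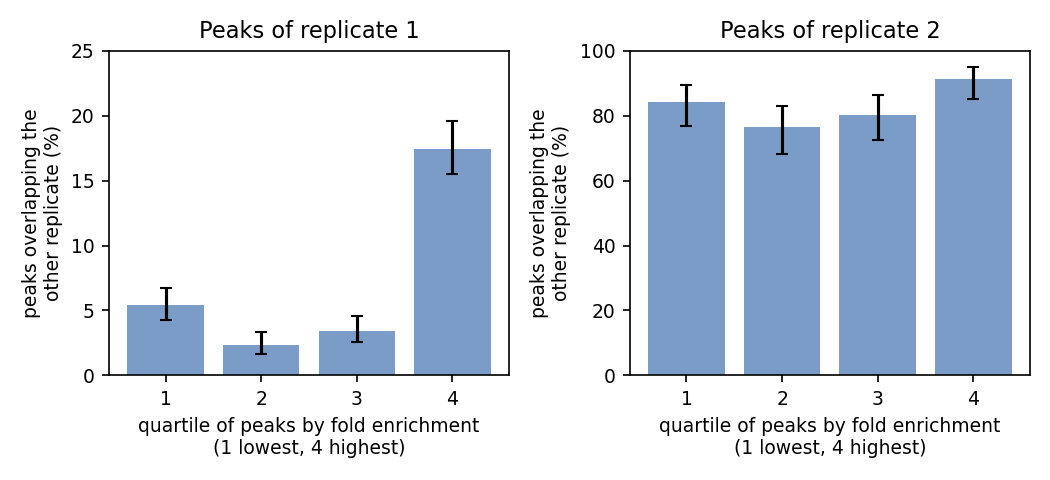
Share of each replicate's peaks that overlap a peak of the other replicate (percent, vertical axis), by quartile of the authors' fold enrichment (horizontal axis, 1 lowest to 4 highest); bars are shares and error bars 95% Wilson intervals. The vertical axes differ: replicate 1 reaches 17.4% in its highest quartile, whereas replicate 2 lies between 76.4% and 91.4% in every quartile.

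The strongest replicated peaks lay at or near a few genes and on contigs outside the chromosome sequences. Among the 20 replicated peaks with the highest fold enrichment, 9 were on such contigs and 11 were on chromosomes. The strongest was in an intron of Asmt, the last enzyme of melatonin synthesis, on chromosome X (mm10, 170674244 to 170675327), with a fold enrichment of 10.1 in the replicated list, 10.7 in replicate 1 and 7.25 in replicate 2. A second Asmt peak (170675492 to 170678076) reached 7.01. The next on a chromosome lay 2890 bases upstream of the mucin gene Muc3 on chromosome 5 (137151859 to 137152564; 8.54). It was followed by a peak of 3445 bases over the last exon of Zfp180 on chromosome 7 (24103973 to 24107417; 7.61) and by one 14004 bases from the start of the pseudogene Mid1-ps1 on chromosome Y (90737484 to 90740622; 7.26). Others lay 1778 bases upstream of Ppia, the gene of cyclophilin A, on chromosome 11 (6413439 to 6413890; 7.12), and in introns of Tpm1, which encodes a tropomyosin, on chromosome 9 (67034830 to 67035505; 6.30) and of the predicted gene Gm49319 on chromosome 14 (46538992 to 46539736; 6.37). The remaining ones lay 24098 bases from the start of Pisd-ps1 (chromosome 11, 3101135 to 3102477; 6.67), 14361 bases from that of Vmn1r-ps2 (chromosome 4, 3089426 to 3091035; 6.58) and 53176 bases from that of Gm29277 (chromosome Y, 259210 to 259443; 6.30). All of these were also peaks of both replicates' own lists except the last, which replicate 1 lacked.

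Zinc finger genes carried many of the replicated peaks, 114 of the 1215 on chromosomes. Of 426 protein-coding members, 61 (14.3%) had a replicated peak in the gene or within 5 kb, against 6.15 in rotations, an excess of 9.92 times (permutation, adjusted p = 0.0013, the smallest possible for 2 of 13 lists). These genes encode DNA-binding proteins, many of which recognise retroelements and recruit the machinery that writes H3K9me3. The marked members lay on 16 chromosomes, with 17 of 107 on chromosome 7 and 8 of 32 on chromosome 4. The strongest peak was over a coding exon in 31 of the 61. For Zfp180 it spanned the whole of the last coding segment (24104405 to 24106122). The other members with the highest fold enrichment were Zfp112, 5 kb or less from the same peak, Zfp784 and Zfp865, which share a peak on chromosome 7 (5029778 to 5031414; 5.89), Zfp810 on chromosome 9 (22278138 to 22279278; 5.53), Zfp988 on chromosome 4 (147338153 to 147338598; 5.51), Zfp763 on chromosome 17 (33018876 to 33019735; 5.37) and Zfp992 on chromosome 4 (146456424 to 146456796; 5.33). By the replicates' own lists, 106 members had a peak in replicate 1, 34 in replicate 2 and 33 in both. These counts are per gene: the named peak of Zfp988 overlapped no replicate 2 peak. The excess was 4.18 times in replicate 1 alone and 12.5 times in replicate 2 alone. Against random genes of matched length the excess in the replicated list was smaller, at 6.35 times (permutation, adjusted p = 0.000867). Similar members of the family can share reads, which the lists do not show.

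**Figure D2:**
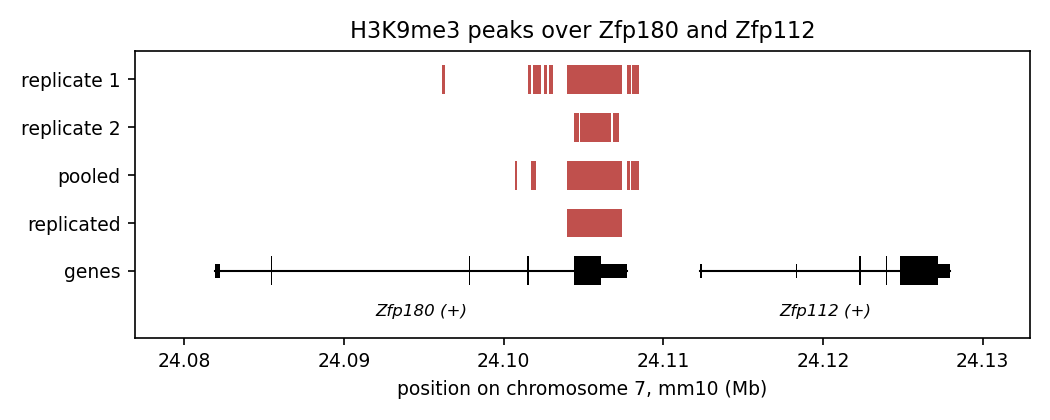
Peaks of the 4 lists (red boxes) over Zfp180 and Zfp112 on chromosome 7; the horizontal axis is the position in mm10 (Mb), tall black boxes are coding exon parts, low boxes untranslated exon parts and the line the gene body. The replicated peak from 24103973 to 24107417 covers the last coding segment and most of the last exon of Zfp180, and both replicates' own lists have a peak there.

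Imprinted genes, which are expressed from 1 parental copy, were the other list with an excess. Of 43 members, 13 (30.2%) had a replicated peak, against 0.859 in rotations, an excess of 15.1 times (permutation, adjusted p = 0.0013). Against random genes of matched length the excess was 11.6 times (permutation, adjusted p = 0.000867). Because neighbouring imprinted genes share peaks, these 13 rest on 9 different strongest peaks on 6 chromosomes. Fold enrichment was highest 3.43 kb upstream of Igf2, a fetal growth factor gene (chromosome 7, 142669837 to 142670648; 5.26). It was 4.65 in an intron of Impact (chromosome 18, 12973673 to 12974009) and 4.26 over a coding exon of Cdkn1c, a cell cycle inhibitor gene (chromosome 7, 143460025 to 143461295). The shared peak of Gnas and its antisense transcript Nespas (chromosome 2, 174285176 to 174285529) had 4.17, that of Kcnq1 and its antisense RNA Kcnq1ot1 (chromosome 7, 143250563 to 143250876) had 3.88, and an intron of the growth regulator gene Grb10 (chromosome 11, 12025966 to 12026211) had 3.84. The other members were Mest, Peg3, Usp29, Airn and Igf2r. Their names, outside the fixed rule, were taken after their values were seen. Replicate 1 had a peak at 18 members (4.96 times rotations), replicate 2 at 10 (23.2 times), and both at 10. These counts are per gene and not per peak. Of the strongest peaks, those of Igf2, of Gnas and Nespas, and of Mest overlapped peaks of both own lists. Those of Impact, of Cdkn1c, of Kcnq1 and Kcnq1ot1, and of Peg3 and Usp29 overlapped replicate 1 alone. That of Grb10 overlapped replicate 2 alone, and that of Airn and Igf2r overlapped neither.

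Genes of the cell types in the organ were mostly free of replicated peaks. Of 40 hepatocyte genes only Amd1, a gene of polyamine synthesis that most tissues use, had one (chromosome 10, 40306074 to 40306462; 3.65), of 39 erythroid genes only the transcriptional cofactor gene Zfpm1 (chromosome 8, 122335821 to 122336972; 4.28), and none of 35 genes of other blood cells or 22 endothelial and mesenchymal genes. These counts did not differ from rotations, which gave means of 0.423 to 0.685 (permutation, adjusted p from 0.992 to 1), so the lists are too short to show a depletion. In replicate 2's own list 2 erythroid genes had a peak against 0.216 in rotations (9.25 times), which did not pass the test either (permutation, adjusted p = 0.125). Of 32 neuronal genes, Syt1, Tubb3 and Slc17a7 had a peak, 3.61 times the 0.832 of rotations (permutation, adjusted p = 0.277). Of 30 muscle genes, Ttn, with 6 peaks, and Myh8, with 1, were overlapped, 3.27 times the 0.612 of rotations (permutation, adjusted p = 0.640). Neither list passed the test, and in replicate 1's own list the ratios were 1.65 and 1.39. None of 39 Hox genes had a peak, against 0.251 in rotations (permutation, adjusted p = 1). Of 50 germline genes, Dazl, which encodes a germ cell RNA-binding protein, had a peak 0.083 kb from its transcription start (chromosome 17, 50293136 to 50293969; 4.25), and Meioc had one in an untranslated part (chromosome 11, 102665520 to 102665933; 2.77). This list did not pass the test (permutation, adjusted p = 0.673), although 6 members had a peak in the pooled list, where it did (adjusted p = 0.0459).

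Few members of the large receptor families had a replicated peak. They were 3 of 1134 olfactory receptor genes (Olfr769, Olfr771 and Olfr772, all on chromosome 10) and 1 of 328 vomeronasal receptor genes (Vmn1r238), against 7.09 and 3.30 in rotations (permutation, adjusted p = 0.673 for both). For the olfactory receptors this was 0.423 times, against 0.619 in replicate 1's own list and 0 in replicate 2's, and for the vomeronasal receptors 0.303 times, against 0.803 and 0.630, none of which passed. Against random genes of matched length, which ignore clustering, the olfactory receptors were lower, at 0.242 times (permutation, adjusted p = 0.00195). Of 56 clustered protocadherin genes, which encode neuronal adhesion proteins, 17 counted as overlapped, among them Pcdhga1, Pcdhga10, Pcdhga11, Pcdhga2, Pcdhga3, Pcdhga4, Pcdhga5 and Pcdhga6. All 17 share 1 peak on chromosome 18 (37756501 to 37756718; 3.22), and the list did not pass the test (permutation, adjusted p = 0.218). It passed against random genes of matched length (7.96 times) and in replicate 1's own list, where 43 members had a peak (8.02 times; permutation, adjusted p = 0.000867 for both). It fell to 0 with the 50% of peaks of higher −log10 p.

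**Figure D3:**
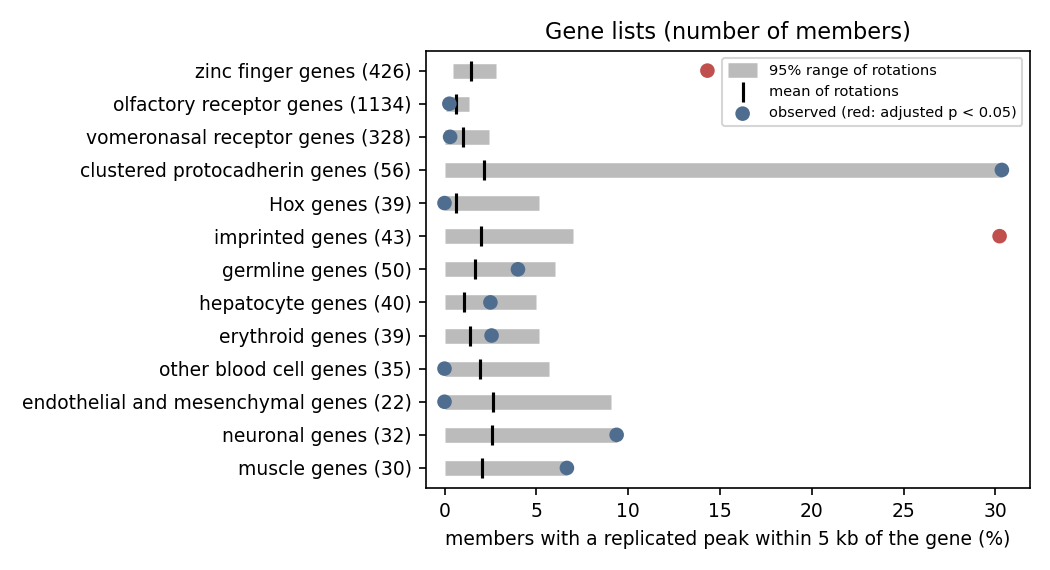
Percent of each list's members with a replicated peak within 5 kb of the gene (horizontal axis), for the 13 lists (vertical axis, number of members in brackets); dots are observed shares, black ticks the mean and grey bars the 95% range of 10000 rotations. Zinc finger genes (14.3%) and imprinted genes (30.2%) lie above their ranges, and the protocadherin genes (30.4%) lie at the upper end of theirs.

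Replicated peaks were found in exons and near transcription starts more often than by chance. Exons held 173 of the 1215 peaks on chromosomes (14.2%, 95% Wilson interval 12.4 to 16.3), against 3.13% in rotations, an excess of 4.55 times. Promoters, taken as 1 kb to either side of a transcription start, held 9.22% (7.72 to 10.98) against 4.57%. Intergenic sequence held 35.6% (33.0 to 38.4) against 50.1%. Each of these had a permutation adjusted p of 0.000267, the smallest possible for 3 of 4 classes. Introns held 40.9% against 42.2% and did not differ (permutation p = 0.649). In replicate 1's own list the excess was 2.84 times for exons and 1.27 times for promoters, and the intergenic share was 0.965 times that of rotations and no longer lower by the permutation test (adjusted p = 0.317). The rotations do not match G+C content, in which the peaks were rich. Nor were the feature classes tested without the 114 peaks at zinc finger genes.

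Counted by covered bases, 4 of the 10 leading protein-coding genes lay in or next to the 2 densest windows of 100 kb. Drg1, which encodes a GTP-binding protein (10113 bases in 11 peaks), and Sfi1, a centrosomal protein gene (7503 bases in 8 peaks), overlap each other on chromosome 11, and Mroh2a (7708 bases in 19 peaks) and the cold-sensing channel gene Trpm8 (4132 bases in 11 peaks) lie close together on chromosome 1. Fold enrichment was modest there, with a maximum of 2.54 in Drg1, 3.28 in Sfi1, 2.69 in Mroh2a and 3.204 in Trpm8. No list of high-signal artefact regions was used here, so it is open whether these counts reflect H3K9me3. The others were Gm20388 (5260 bases), whose annotated body of 4434882 bases spans many other genes, Trim56 (4962), Asmt (4542), Il3ra (3959), Mid1 (3797) and Zfp180 (3445). Each of the 10 genes was also covered in both replicates' own lists, which a recurrent artefact would give too. Although replicate 1 lists far more peaks, replicate 2 had more at Drg1 (13 against 8), Sfi1 (10 against 7) and Trim56 (5 against 2). Asmt had 4 in each, and replicate 1 had more peaks at the other genes. Replicate 1 covered more bases at each of the 10, by little at Drg1 (10854 against 9415) and by much at Mroh2a (9380 against 1876). In all, 438 of 21938 protein-coding genes had a replicated peak in the body.

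Peaks were spread unevenly over the chromosomes. Chromosome 17 had 96 peaks, 2.28 times the number implied by its length (exact binomial test, adjusted p = 5.51e-12), and chromosome 5 had 124, 1.83 times (adjusted p = 1.88e-09). Chromosomes 11 (1.52 times, adjusted p = 0.000667) and 4 (1.48 times, adjusted p = 0.000431) were also higher by the exact test. Chromosome Y had 5 peaks, 0.124 times its share (exact test, adjusted p = 3.82e-11; 0.0171 times in replicate 1's own list and 0.354 in replicate 2's), X had 28 (0.373 times, adjusted p = 2.03e-09) and chromosome 3 had 28 (0.390 times, adjusted p = 1.12e-08). Chromosomes 16 (0.596 times), 18 (0.648 times), 14 (0.664 times) and 6 (0.715 times) were lower with exact adjusted p between 0.0139 and 0.0379. The expected numbers rest on length alone. They allow neither for the number of X and Y copies in pools of both sexes nor for sequence that short reads cannot place. The low X and Y counts therefore do not show that these chromosomes carry less of the mark. The test treats peaks as independent, and they cluster: with peaks within 10 kb merged, 7 chromosomes passed in place of 11, and chromosome 4 stood at 1.20 times without passing (exact test, adjusted p = 0.216). In replicate 1's own list chromosome 11 turned to 0.942 times and chromosomes 16 (0.855 times) and 18 (0.843 times) did not pass. In replicate 2's own list chromosome 18 turned to 1.07 times, chromosome 16 was the lowest of the named ones at 0.219 times, and chromosomes 14 (0.814 times) and 6 (0.746 times) did not pass. Without the 2 densest windows, on chromosomes 1 and 11, chromosome 11 stood at 1.24 times and no longer passed (exact test, adjusted p = 0.1002), nor did chromosomes 6 and 18.

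**Figure D4:**
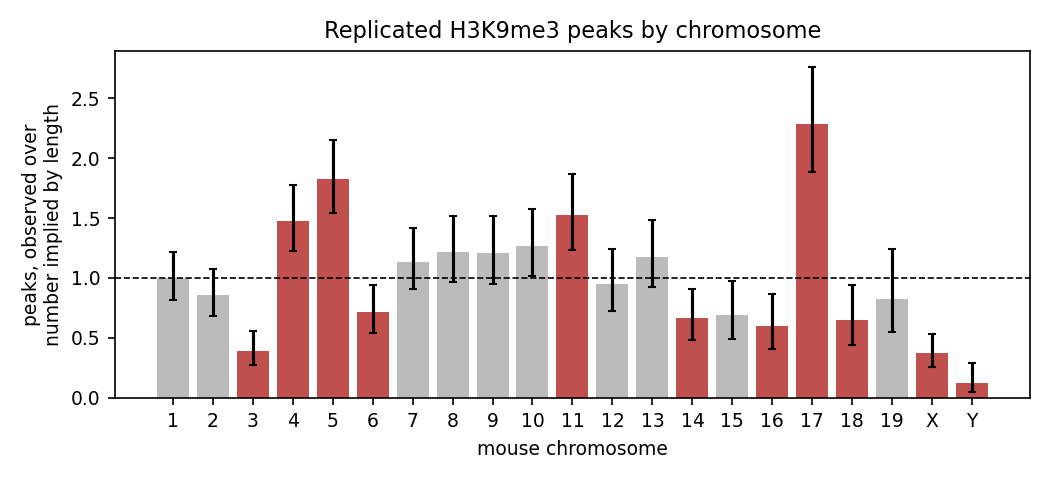
Number of replicated peaks on each mouse chromosome (horizontal axis) divided by the number implied by its length without assembly gaps (vertical axis); error bars are 95% Wilson intervals, the dashed line marks 1 and red bars passed the exact binomial test after adjustment. Chromosome 17 stands highest at 2.28 times and chromosome Y lowest at 0.124 times.

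The centromere end of the chromosomes was tested because pericentromeric heterochromatin carries this mark. The first 10 Mb of the autosomes and X held 6.86% of peaks (95% Wilson interval 5.57 to 8.42) against 5.49% in rotations, which did not pass the test (two-sided permutation p = 0.427). The first 5 Mb held 4.79% against 1.54%, which did (3.11 times, permutation p = 0.0192). Of these 58 peaks, 18 lay in 1 dense window of chromosome 11 (3100001 to 3200000). The excess was 2.22 times without the 2 densest windows (permutation p = 0.0712) and 1.94 times with peaks within 10 kb merged (permutation p = 0.0512), and passed the test in neither. Satellite repeats themselves are largely missing from the assembly.

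By sequence, the peaks were rich in G+C and CpG, and some lay near retroviral primer binding sites. Mean G+C content was 47.7% against 42.1% in rotations, and the CpG ratio of observed over expected was 0.312 against 0.195. Repeat-masked bases made up 25.2% of peaks, fewer than the 33.9% in rotations. Each had a permutation adjusted p of 0.0035, from a raw p of 0.002, the smallest possible. A primer binding site is the 18-base stretch where a tRNA starts reverse transcription of a retrovirus. The site for proline tRNA (TGGGGGCTCGTCCGGGAT) lay within 5 kb of 25 peaks against 0.675 in rotations, 37.0 times (permutation, adjusted p = 0.0014, the smallest possible). The excess was 16.6 times in replicate 1's own list. Of the 174 copies of the site on the chromosomes, 15 had a replicated peak within 5 kb (8.62%, interval 5.29 to 13.7; 15.5% in replicate 1's own list and 3.45% in replicate 2's), and 4 peaks overlapped a copy themselves. The site for phenylalanine tRNA (TGGTGCCGAAACCCGGGA) lay near 15 peaks against 5.08 (permutation, adjusted p = 0.0359). The second lysine form, here called Lys3 (TGGCGCCCGAACAGGGAC), lay near 4 against 0.296 (permutation, adjusted p = 0.0333), and the other, Lys1,2 (TGGCGCCCAACGTGGGGC), near 1 against 0.344 (permutation, adjusted p = 0.438). Counted by copies of the site, 10 of 1090 for phenylalanine and 2 of 62 for Lys3 had a replicated peak within 5 kb. In replicate 2's own list, sites for phenylalanine lay near 6 peaks against 2.08 (permutation, adjusted p = 0.202) and Lys3 sites near none, so neither call held there. Without the 2 densest windows phenylalanine sites lay near 10 peaks against 4.89 and did not pass (permutation, adjusted p = 0.1995). Copies in repeats that short reads cannot place uniquely are not measured by such lists.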

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

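The tests of peaks on contigs and of zinc finger genes among peaks of replicate 1 alone were chosen after the result was seen; the others here were set before. With 1 group and 2 samples, no biological explanation was tested for the patterns weighed here.

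Peaks on contigs outside the chromosome sequences, unplaced or assigned to a chromosome without a position, were set apart because the location and replicate overlap tests leave them out. They made up 9.73% of the replicated list, 3.01% of replicate 1, 17.1% of replicate 2 and 6.43% of the pooled list. In the replicated list this was 131 peaks, 24.97 per Mb against 0.459 per Mb on the chromosomes, a ratio of 54.4 (15.7 in replicate 1's own list and 104.1 in replicate 2's), and 60 of them lay on 3 contigs. A candidate explanation is that these contigs stand for many repeat copies in the genome, which raises coverage in sample and control alike. At a matched fold enrichment their −log10 p was higher than on chromosomes by a mean of 1.46 (permutation p = 0.0002, the smallest possible), which this explanation needs. The test treats peaks as independent, but the 131 lie on only 13 contigs, so the p-value may be too small. H3K9me3 on these repeats may add to the density of peaks, and the lists alone do not separate it from raised coverage.

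The 8.86 times larger number of peaks in replicate 1 could be background in that list. The 4900 replicate 1 peaks without a replicate 2 partner overlapped 100 zinc finger genes, 4.06 times the number in rotations (permutation, adjusted p = 0.000867). Background placed without regard to these genes would not give this excess. Background from reads shared between similar zinc finger genes could, so the test does not decide on background of that kind. A peak without a partner can also lie beside a shared peak, as at Zfp180 (24107718 to 24107992). A part of them may still be background. Another explanation is that replicate 2 detected only the strongest part of the same signal: 30.5% of the top 10% of replicate 1 peaks by fold enrichment overlapped replicate 2, against 4.55% of the rest, although most of that top 10% was not found in replicate 2. A difference in the further files behind each list cannot be told apart from the replicate, because 1 list was made with each set.

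For the excess at zinc finger genes, G+C content was weighed, since peaks were rich in G+C. With placement matched on the G+C content of 500-base windows, these gene windows still held 114 peaks against 9.05, or 12.6 times (95% interval 9.17 to 16.3 by resampling groups of peaks within 10 kb), so G+C content is not the whole cause. Whether reads shared between similar zinc finger genes add to it stays open, since the lists hold no reads.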

How the results depend on the processing

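The list of replicated peaks present in both own lists, the list without the 2 densest windows, and the first 5 Mb with that list or with merged peaks were chosen after seeing the data. Over 341 alternatives to 45 results, 271 kept direction and side of the threshold or, for plain counts of peaks or of chromosomes that passed, stayed within 1.5 times. These include merging within 10 kb for the 13 gene lists, which could change nothing there because every gene window is wider than 10 kb. Merging is therefore no test of the gene lists. The 271 also include results that passed neither in the main setting nor in the alternative, such as Hox genes, which stood at 0 throughout. Such rows put no excess to the test. Zinc finger genes (4.18 to 14.8 times), imprinted genes (4.96 to 36.3), promoters (1.27 to 2.61), exons (2.84 to 5.27) and proline sites (16.6 to 142.3) kept direction and side of the threshold in each, as did replicate overlap and base composition. Chromosomes 3, 5, 17, X and Y also kept theirs, each against length alone. Replicate depth is unknown and limits every count. No paired analysis was possible because there is 1 group. The causes of the changes below were not tested, except that halving a list or merging peaks lowers counts by construction.

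With replicate 1 or 2 left out, ranges over rotations were 0.877 to 1.06 for introns, 0.555 to 0.965 for intergenic sequence, 0 to 0.566 for hepatocyte genes, 1.86 to 9.25 for erythroid genes, 0.630 to 0.803 for vomeronasal and 0 to 0.619 for olfactory receptor genes, 1.65 to 5.22 for neuronal and 1.39 to 3.96 for muscle genes, 8.02 to 21.9 for protocadherin genes, 2.89 to 3.07 for Phe sites, 0 to 6.96 for Lys1,2, 0 to 5.85 for Lys3 and 0.741 to 1.76 for the centromere-proximal share. Introns, protocadherin genes and Lys1,2 sites passed in replicate 1's own list, where intergenic sequence did not, and Phe sites did not in replicate 2's. Chromosome 18 ranged from 0.843 to 1.07, 11 from 0.942 to 2.01, 16 from 0.219 to 0.855 and Y from 0.0171 to 0.354. With the 50% of peaks of higher −log10 p, introns turned to 1.05, hepatocyte and protocadherin genes and Lys1,2 sites to 0, Lys3 sites stood at 13.3 without passing, 6 chromosomes passed in place of 11, and lists held 2720, 307, 1283 and 673 peaks (replicate 1, replicate 2, pooled, replicated). Chromosome 4 stood at 1.32 there, 1.20 with merged peaks and 1.22 with peaks in both own lists, without passing. Merging within 10 kb left 358 peaks in replicate 2, 1620 pooled and 840 replicated, 7 chromosomes, and a centromere-proximal share of 0.944. With peaks in both own lists, introns turned to 1.04, hepatocyte and protocadherin genes and both lysine sites to 0, Phe sites stood at 3.2 without passing, and 7 chromosomes passed. Without the 2 densest windows, Phe sites stood at 2.04 without passing, as did chromosomes 6, 11 and 18 (0.745, 1.24 and 0.676).

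Gene body alone gave 0 for hepatocyte genes, and 5 kb around the start gave 0 for erythroid, neuronal and muscle genes. Newly past the threshold were germline genes in the pooled list (3.87), olfactory receptor (0.242) and protocadherin genes (7.96) against random gene sets, the first 5 Mb (3.11, but 2.22 without the 2 densest windows and 1.94 merged, neither passing), and strength by −log10 p in replicate 2 (0.734). With 2 mismatches Lys3 sites fell to 2.57 without passing. In the peak alone, Phe and both lysine sites gave 0.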

Other observations

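The test of position along zinc finger genes was set before its result was seen; the regions below were picked after seeing the data.

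Some regions held many replicated peaks. The densest 100 kb held 32 peaks, on chromosome 1 from 88200001 to 88300000. Of these, 19 overlapped Mroh2a, and the window also holds Hjurp, part of Trpm8 and genes of the Ugt1a cluster, which encode enzymes that conjugate bilirubin and drugs. Next came chromosome 11 from 3100001 to 3200000 at Sfi1 and Drg1 with 18 peaks, and chromosome 17 from 13200001 to 13300000 at the sperm motility kinase genes Smok2a and Smok2b with 14. Fold enrichment reached 2.69 in Mroh2a, 2.54 in Drg1 and 3.28 in Sfi1, below the median of 3.50 over the replicated list, although the chromosome 11 window also holds the peak of 6.67 near Pisd-ps1. No list of high-signal artefact regions was used here, so whether the first 2 windows are such regions stays open. A stretch of chromosome 7 (30100001 to 30200000) with Zfp260, Zfp382 and Zfp146 held 10. In replicate 1's own list, 43 of 56 clustered protocadherin genes had a peak within 5 kb, from 21 peaks, whereas replicate 2 had 1 peak there, counted for 17 genes.

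A hypothesis was that the mark follows the 3' part of zinc finger genes, where the finger-coding exon usually lies. The median relative position of 106 replicated peaks inside these genes was 0.816, with 0 at the 5' end and 1 at the 3' end (two-sided permutation p against uniform positions = 0.0002, the smallest possible). The median lay past the middle of the gene in 45 of 54 genes. It was 0.786 in replicate 1's own list and 0.827 in replicate 2's. Peaks in the same gene are not independent, so the p-value is too small, and the values are consistent with the hypothesis without showing which sequence carries the mark.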
